A study of Mus musculus with 18 samples.

How the data were processed

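The deposited counts are raw uniquely mapped reads per gene, made by the authors with STAR 2.5.1b on GRCm38 after bcl2fastq 2.17, per the submitters' processing notes. Each count file holds columns for unstranded, forward and reverse counting, and the reverse column was used because 92.8 to 95.3% of the stranded gene counts fall there. The deposited expected counts and the deposited TPM come from RSEM 1.2.28, per the file headers and the submitters' notes, and serve as alternatives. CPM were computed here from the counts with TMM-scaled library sizes. Libraries are poly-A selected and stranded, per the labels.

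All 18 libraries were used, 3 in each of 6 groups, and groups were set from the sample labels before the data were examined. The libraries held 23.6 to 31.2 M reads in all (M, 1e6), of which 17.5 to 23.4 M were counted in genes. Between 21.7 and 35.8% of reads fell in the summary lines for unmapped, multimapping, ambiguous and outside-gene reads, which were left out of the tests. Between 18547 and 19239 genes had a count in a library. No library was a copy of another: the squared difference between replicates over its counting variance ran from 7.98 to 87.2. Of 50600 gene identifiers 50376 matched the GENCODE M21 annotation after the version suffix was removed, which gave symbols and positions.

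Differential expression used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its defaults and the 6 groups, which left 13939. TMM factors, robust dispersions and robust quasi-likelihood fits came from 1 model with a mean for each group (residual degrees of freedom 12, common biological coefficient of variation 0.110, median prior degrees of freedom 6.17). Tests were made for 11 contrasts: DM2 against GM in each line, each depleted line against control and the depleted lines against each other in each medium, and the difference of each depleted line's response from that of control. P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene is called under 0.05. The standard error of a log2 fold change is its size over the square root of the quasi-likelihood F. Log2 CPM used a prior count of 2.

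Gene lists were written from general knowledge before the data were examined: 28 lists, of which 6 are primary (sarcomere, myogenic regulators, fusion, calcium handling, cell cycle and FoxO targets) and 8 hold markers of other cell types. The 25 lists with at least 5 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, and the 275 list tests were adjusted together. They were repeated with the correlation estimated from the data and with fry. Of the 275 tests 111 were called by camera, 80 of these also by fry, and none with the estimated correlation (smallest adjusted p 0.174). For ERK3 against control fry did not make 4 of the 11 camera calls in GM and 1 of the 6 at DM2. For MK5 against control it did not make 2 of the 9 in GM and 0 of the 9 at DM2. The count adjusted over the list alone applies Benjamini-Hochberg to the members only. The sarcomere level of a library is its mean log2 CPM over tested members, compared by exact permutation, with a smallest two-sided p of 0.1.

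Genes are named by rule, and some genes it picks are not reported here. In each comparison these are Mapk6, Mapkapk5 and Foxo3, up to 4 called members with the largest fold change of each primary list (or the member nearest to a call), up to 3 of each other called list, and the 5 rising and 5 falling most. These last need a mean of at least 5 CPM in the higher group, a gene symbol that is not a clone or predicted-gene name, and no overlap between the libraries of the groups, a condition not set for the interactions. Fbxo32 and Trim63 are given in every depletion comparison.

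Alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, a model with only the libraries of the contrast, the replicate number as a block in the whole model or within each line, an adjusted p under 0.01, a glmTreat test against 1.5-fold, RSEM expected counts (rounded first), limma-trend on log2(TPM + 1) with a filter of 1 TPM, and each library left out in turn. Chosen after seeing the data were unstranded counts, offsets that remove each library's trend with gene length and GC content (natural splines with 5 degrees of freedom), the same offsets with the block, the share of reads outside genes as a covariate, and the 4 DM2 libraries with the most such reads left out (ERK3-depleted 1 and 2, MK5-depleted 1 and 2). This last fit leaves n = 1 in each depleted DM2 group and takes its spread from the other groups, so only its counts of calls are given. Reads outside genes are counted here without regard to strand. TPM were compared as deposited, without TMM or other scaling between libraries, so a shift of most genes between groups stays in their fold changes.

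Pairing by replicate number was checked as the correlation, across genes, of deviations from group means between libraries with the same number. It ran from 0.156 to 0.291 for DM2 against GM in the ERK3 line, 0.155 to 0.290 for ERK3 against control in GM, 0.108 to 0.205 at DM2, 0.142 to 0.190 for MK5 against control in GM and 0.281 to 0.498 between the depleted lines at DM2, with 6 of 6 libraries closest to their own number in each. It did not hold for DM2 against GM in control (-0.021 to 0.172) or the MK5 line (-0.092 to 0.222), with 2 of 6 libraries closest to their own number in each. It held in part for MK5 against control at DM2 (0.055 to 0.165) and between the depleted lines in GM (0.070 to 0.344), with 5 of 6 libraries closest in each. The labels do not state pairing, so the model has no block.

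The resemblance of both depletions was set beside 100 simulated draws, in which the control and the unchanged depleted groups share 1 mean per gene and both comparisons share the drawn controls. The response size is the principal-axis slope over genes called from GM to DM2 in any line, with a jackknife standard error over libraries. For each 3 against 3 contrast all 10 splits of the 6 libraries were tested, and 100 splits, the real grouping among them, for each interaction.

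The functions were run on simulated counts with 200 changed genes of mean count at least 10 in each depletion comparison. They recovered 49.3 to 59.7% of genes changed 1.5-fold, 85.1 to 86.6% at 2-fold and 93.9 to 100% at 4-fold, with 4 to 12 false calls. With a simulated length trend, 79 to 107 genes were called before the offsets and 0 after. Of 25 lists tested, the 1 shifted by 0.5 log2 was found and 0 others were called. Genes were drawn independently, so this does not test list calls among correlated genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.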

Results

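C2C12 cells are mouse myoblasts that leave the cell cycle and fuse into myotubes when growth factors are withdrawn. By its labels the series holds 3 stable lines of them: a control line, a line depleted of ERK3 and a line depleted of MK5. ERK3 is an atypical MAP kinase encoded by Mapk6, and MK5 a kinase that binds ERK3, encoded by Mapkapk5. Each line was sequenced in growth medium (GM), where the cells divide, and after 2 days in differentiation medium (DM2), with 3 libraries per group and 18 in all. The libraries held 17.5 to 23.4 M counts in genes (M is 1e6), and 13939 genes were tested. A gene is called where its Benjamini-Hochberg adjusted p from the edgeR quasi-likelihood test lies under 0.05. Nothing in the labels says whether the replicates are separate cultures or separate clones, so every p-value measures only the spread between these samples.

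Mapk6, the gene targeted in the ERK3-depleted line, stood at 131 ± 17.0 CPM (counts scaled to 1e6 per library, mean ± SD, n = 3) in control GM and 118 ± 14.0 in ERK3-depleted GM. The log2 fold change between them was -0.15 ± 0.12 (± standard error) and was not called (edgeR adjusted p = 0.464). The single GM libraries read 150, 119 and 124 in control, 115, 105 and 133 in ERK3-depleted, and 174, 142 and 175 in MK5-depleted cells (log2 fold change 0.32 ± 0.12 for MK5, adjusted p = 0.105). At DM2 Mapk6 held 219, 207 and 204 CPM in the control libraries, 116, 96.8 and 136 in the ERK3-depleted ones (log2 -0.85 ± 0.12, 1.81-fold lower, adjusted p = 2.18e-05) and 161, 153 and 163 in the MK5-depleted ones (log2 -0.40 ± 0.12, adjusted p = 0.0115). The change from GM to DM2 differed from control by -0.70 ± 0.17 (adjusted p = 0.00788) in the ERK3 line and by -0.72 ± 0.17 (adjusted p = 0.0123) in the MK5 line. The MK5 call at DM2 was lost without MK5-depleted DM2 library 2 (adjusted p = 0.0502) and, in a test chosen after seeing the data, with the trend with gene length and GC content removed (-0.14, adjusted p = 0.250). If the depletion was made with a guide RNA, which acts on the DNA, the RNA of the edited gene need not be lower. The gene lies on chromosome 9 at 75369062 to 75410005, minus strand (ENSMUSG00000042688.16, GENCODE M21 on GRCm38).

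Mapkapk5, the gene targeted in the MK5-depleted line (chromosome 5, 121525038 to 121545905, minus strand, ENSMUSG00000029454.15), received only 11 to 32 reads per library. Its span overlaps that of Gm42878 (ENSMUSG00000105340.4, 121518613 to 121545482), a protein-coding gene model on the same strand. Whether reads shared by both were left out as ambiguous was not analysed here. The 11 to 32 counted reads are few beside the 590 to 1177 expected counts that RSEM gave per library. On these few reads the MK5 line gave a log2 fold change of -0.55 ± 0.27 at GM (edgeR adjusted p = 0.232) and -0.68 ± 0.26 at DM2 (adjusted p = 0.0443). RSEM gave 55.5 ± 3.46 TPM (RSEM transcript abundance, n = 3) in control GM and 33.3 ± 2.40 in MK5-depleted GM, a log2 fold change of -0.68 on its expected counts (adjusted p = 0.000246). At DM2 the RSEM levels were 69.2 ± 3.19 TPM in control and 49.1 ± 8.12 in MK5-depleted cells, with a log2 fold change of -0.08 on expected counts (adjusted p = 0.348). The DM2 call on reads was lost without MK5-depleted library 1 or 2 (adjusted p = 0.0803, 0.182) and without control library 1 or 3 (0.161, 0.0985), and DESeq2 did not make it (-0.68, adjusted p = 0.112). In the ERK3 line the gene's fold change was -0.51 ± 0.28 at GM (adjusted p = 0.275) and -0.57 ± 0.26 at DM2 (adjusted p = 0.0751) on reads, and 0.11 and 0.30 on RSEM counts.

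Foxo3, the transcription factor named in the series title (chromosome 10, 42181841 to 42276755, minus strand, ENSMUSG00000048756.11), was lower in both depleted lines and both media, by 1.24-fold to 1.37-fold. Its level was 67.4 ± 5.26 CPM in control GM and 69.5 ± 2.80 in control DM2, against 53.3 ± 5.51 and 53.6 ± 5.42 in the ERK3 line and 54.4 ± 1.24 and 50.6 ± 2.84 in the MK5 line (n = 3 each). The log2 fold changes were -0.34 ± 0.09 (edgeR adjusted p = 0.0315) and -0.37 ± 0.09 (adjusted p = 0.00192) for ERK3, and -0.31 ± 0.09 (adjusted p = 0.0399) and -0.46 ± 0.09 (adjusted p = 0.000643) for MK5, at GM and DM2 in turn. RNA does not report the amount of FoxO3 protein. The alternatives in the next sentence were chosen after seeing the data. The ERK3 difference at DM2 was -0.15 (adjusted p = 0.124) after the trend with gene length and GC content was removed and -0.17 (adjusted p = 0.338) with the share of reads outside genes as a covariate. At GM the ERK3 call was lost without control library 2 or 3 or ERK3-depleted library 1 or 3, and the MK5 call without control library 2 or 3 or any 1 MK5-depleted library.

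Over 2 days of differentiation the control line went from a proliferating to a muscle-like RNA profile. Myog, the transcription factor that commits myoblasts to differentiate, rose 39.1-fold (log2 5.29 ± 0.39, n = 3 against 3), from 15.3 ± 6.25 to 593 ± 90.6 CPM. The fusion proteins Mymk (myomaker) and Mymx (myomixer) rose 43.4-fold and 28.1-fold, embryonic myosin Myh3 68.9-fold and cardiac alpha-actin Actc1 by log2 6.02. Mki67, a proliferation marker, fell 2.66-fold from 192 ± 41.1 to 71.9 ± 8.46 CPM, while Cdkn1a, which encodes the cell cycle inhibitor p21, rose 2.88-fold. In all 6356 genes were called (3140 higher and 3216 lower at DM2, edgeR quasi-likelihood, adjusted p under 0.05), 1670 of them changed over 2-fold.

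Of 42 tested sarcomere genes 40 rose and 0 fell in control cells (40 adjusted over the list alone), with a median log2 fold change of 4.07 (camera adjusted p = 8.67e-27, adjusted p = 0.284 with an estimated correlation). Myoz2, a Z-disc protein, rose 123-fold (log2 6.94 ± 0.53) and the thin filament regulator Lmod2 62.6-fold (log2 5.97 ± 0.37). The mean sarcomere level went from 1.65 ± 0.32 to 5.16 ± 0.07 log2 CPM (exact permutation p = 0.1, two-sided, the smallest possible with 3 against 3). Calcium handling and excitation coupling genes rose in 20 of 22 cases and fell in 0 (21 alone, camera adjusted p = 1.51e-14, adjusted p = 0.234 with an estimated correlation). These include the calcium store protein Casq2 (51.8-fold), the channel subunit Cacna1s (24.5-fold), Kcnn3 (32.8-fold) and Srl (22.4-fold). Neuromuscular junction genes rose in 10 of 12 cases (10 alone, camera adjusted p = 1.27e-08, adjusted p = 0.249 with an estimated correlation). Acetylcholinesterase Ache was 26.4-fold, its collagen tail Colq 19.4-fold and Dok7 21.1-fold higher. Fusion genes rose in 14 of 19 (14 alone, adjusted p = 8.37e-06, adjusted p = 0.284 with an estimated correlation), including the caveolin Cav3 (38.8-fold) and Mgll (3.34-fold). Muscle energy genes rose in 10 of 17 and fell in 3 (10 and 3 alone, adjusted p = 0.00293, adjusted p = 0.305 with an estimated correlation). Creatine kinase Ckm rose 28.1-fold, Cox6a2 29.2-fold and Cox8b 42.4-fold. Myogenic regulators rose in 10 of 21 and fell in 2 (10 and 2 alone, adjusted p = 0.00138, adjusted p = 0.313 with an estimated correlation). Mef2c rose 25.9-fold, Tead4 7.47-fold and Klf5 4.61-fold.

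Cell cycle genes fell in 41 of 45 cases and rose in 0 on control differentiation (41 adjusted over the list alone, median log2 -0.91, camera adjusted p = 3.47e-13, adjusted p = 0.477 with an estimated correlation), with Ccnb2 2.73-fold, Cdc25c 2.62-fold and Cenpa 2.58-fold lower. FoxO target genes split, 14 higher and 9 lower of 32 (14 and 9 alone, median log2 0.20), and the list was not called (camera adjusted p = 0.120). Trim63, a muscle ubiquitin ligase, rose 23.7-fold from 0.620 ± 0.203 to 14.8 ± 0.347 CPM and Irs2 3.15-fold, while Txnip fell 3.87-fold. Foxo3 itself stayed level (log2 0.04 ± 0.09, adjusted p = 0.716), and the value turned to -0.002 without control GM library 1 and to -0.29 (adjusted p = 0.00564) after the length and GC trend was removed. Mapk6 rose 1.60-fold (log2 0.68 ± 0.12, adjusted p = 0.000163) and Mapkapk5 had 0.32 ± 0.25 (adjusted p = 0.307). The largest other changes were Ctrb1 (60.8-fold up), Krt13 (25.5-fold down), Prg4 (17.9-fold down), Lgr6 (16.9-fold down), Acsbg1 (16.6-fold down) and Ptprn (10.3-fold down).

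Secreted and stress-linked groups also changed in control cells. Insulin and IGF genes rose in 14 of 24 cases and fell in 1 (14 and 2 alone, camera adjusted p = 0.000168, adjusted p = 0.174 with an estimated correlation), with the growth factors Igf2 (13.8-fold) and Igf1 (5.29-fold) and the binding protein Igfbp3 (5.36-fold). Extracellular matrix genes rose in 19 of 30 and fell in 1 (19 and 2 alone, adjusted p = 4.02e-05, adjusted p = 0.305 with an estimated correlation), led by Postn (6.41-fold), Ccn2 (3.20-fold) and Col6a2 (2.42-fold). Cholesterol synthesis genes rose in 18 of 25 and fell in 1 (19 and 1 alone, adjusted p = 5.30e-06, adjusted p = 0.496 with an estimated correlation). Insig1 rose 2.73-fold and Cyp51 2.15-fold. ER stress genes rose in 18 of 29 and fell in 4 (19 and 4 alone, adjusted p = 0.000348, adjusted p = 0.496 with an estimated correlation). Chac1 rose 6.18-fold, Slc7a11 2.98-fold and Atf3 3.95-fold, the last not called without control DM2 library 1 (adjusted p = 0.0873), and Slc7a11 turned to log2 -0.44 on unstranded counts. Autophagy genes rose in 17 of 31 and fell in 1 (17 and 1 alone, adjusted p = 0.00269, adjusted p = 0.404 with an estimated correlation). The lysosomal genes Ctsd, Lamp2 and Lamp1 rose 1.69-fold, 1.62-fold and 1.49-fold. Notch and reserve cell genes rose in 13 of 20 and fell in 3 (13 and 3 alone, adjusted p = 0.00264, adjusted p = 0.286 with an estimated correlation). The ligand Dll1 rose 12.2-fold, Spry1 6.75-fold and Sox8 5.31-fold. Interferon response genes fell in 24 of 31 and rose in 0 (25 and 1 alone, median log2 -1.19, adjusted p = 1.77e-06, adjusted p = 0.313 with an estimated correlation), though Oas1a, Ifi44 and Usp18 (log2 -2.53, -2.53, -2.27) stood under 2 CPM in both media. Ribosomal protein genes fell in 22 of 36 and rose in 1 (24 and 1 alone, adjusted p = 0.000393, adjusted p = 0.600 with an estimated correlation), with Rps19 and Rps2 at log2 -0.57 and -0.70. With the length and GC trend removed the list was not called (median -0.21, 14 lower, adjusted p = 0.0535), nor with the replicate block added (0.0702). The Rps2 call was lost without control DM2 library 2 (adjusted p = 0.0527).

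**Figure D1:**
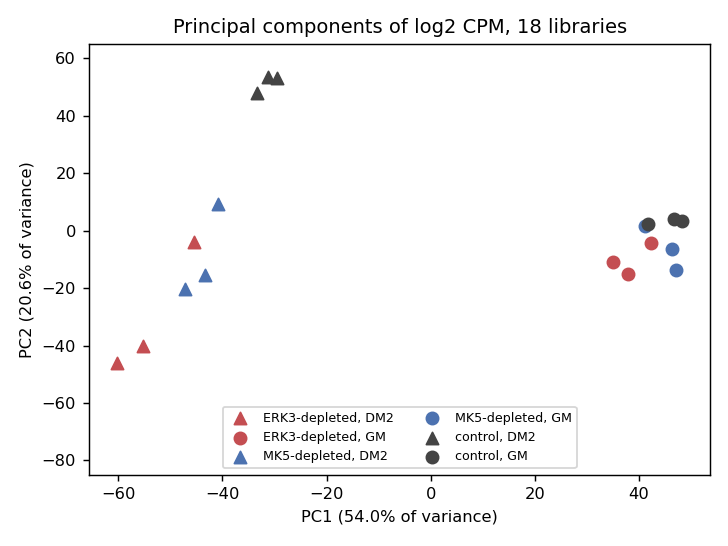
Libraries on the first 2 principal components of log2 CPM, which hold 54.0% and 20.6% of the variance. Each point is 1 library, coloured by group, and control DM2 lies at 48.0 to 53.7 on the second axis.

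In growth medium, cells depleted of ERK3 had more RNA than control cells of some genes for the cell cycle and cholesterol synthesis and of a few regulators of myoblasts. Myod1, the transcription factor that marks myoblasts, was 1.58-fold higher (log2 0.66 ± 0.13, 115 ± 10.3 against 72.9 ± 14.6 CPM, n = 3 each, edgeR adjusted p = 0.0123), and the growth-associated noncoding RNA H19 2.23-fold higher (log2 1.16 ± 0.18, adjusted p = 0.0079). The Id1 and Id2 inhibitors of such factors and the repressor Msc were also higher (1.60-fold, 1.70-fold and 5.51-fold). Scn7a, a sodium channel, was 3.13-fold lower (log2 -1.65 ± 0.26) and Itgb4, an integrin, 3.26-fold lower. In all 946 genes were called, 519 higher and 427 lower, of which 83 differed over 2-fold.

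Cell cycle genes were higher in 14 of 45 cases and lower in 0 (29 alone, median log2 0.46, camera adjusted p = 1.07e-17, adjusted p = 0.381 with an estimated correlation) in ERK3-depleted GM, among them the histone chaperone subunit Chaf1b (log2 0.64 ± 0.11), the nucleotide reductase subunit Rrm2 (0.71 ± 0.19), Cenpa (0.61) and Mcm3 (0.61). Cholesterol genes were higher in 12 of 25 and lower in 0 (21 alone, adjusted p = 5.77e-15, adjusted p = 0.305 with an estimated correlation), with Mvd 0.75, Fdps 0.74 and Insig1 0.73. ER stress genes were higher in 9 of 29 and lower in 1 (16 and 2 alone, adjusted p = 1.36e-06, adjusted p = 0.374 with an estimated correlation), with asparagine synthetase Asns at 0.92 and the cystine transporter subunit Slc7a11 at 1.29, and Vldlr at -1.21. Of the sarcomere genes 4 of 42 were higher and 0 lower (23 and 1 alone, median log2 0.74, adjusted p = 1.53e-09, adjusted p = 0.463 with an estimated correlation): Tnnc2 (1.37), Tnnt1 (0.72), Tnnt2 (0.55) and Des (0.44). The mean sarcomere level differed by 0.63 log2 CPM (exact permutation p = 0.2, without regard to replicate number). Each ERK3-depleted library lay above the control library of its number (2.69, 2.025 and 2.131 against 2.026, 1.493 and 1.442). Myogenic regulators were higher in 4 of 21 and lower in 1 (6 and 2 alone, adjusted p = 0.0450, adjusted p = 0.496 with an estimated correlation), a list call lost without ERK3-depleted library 1 or 3 or control library 2 (adjusted p = 0.0780, 0.156, 0.172) and with the replicate block (0.0571).

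Fusion genes in ERK3-depleted GM had 1 of 19 higher, the cadherin Cdh15 (log2 0.65), and 1 lower, Rnd3 (-0.36), with 1 and 1 alone, a median of -0.09 but a mean of 0.09, and no list call (camera adjusted p = 0.909). None of 22 calcium genes was called, the nearest being Cacna2d1 (-0.35, adjusted p = 0.0913). FoxO targets were lower in 4 of 32 and higher in 2 (4 and 2 alone, median log2 -0.11, adjusted p = 0.0108, adjusted p = 0.286 with an estimated correlation), with Sesn3 at -0.59 and Bcl6 at -0.35 against Eif4ebp1 at 0.44 and Sod2 at 0.38. That list was not called with the length and GC trend removed (median -0.06, adjusted p = 0.0817) or with the replicate block added (0.0805). The ubiquitin ligases Trim63 (0.04 ± 0.32, adjusted p = 0.949) and Fbxo32 (-0.27 ± 0.11, adjusted p = 0.143) were not called. Genes of p53 were lower in 3 of 28 (3 alone, adjusted p = 0.00426, adjusted p = 0.284 with an estimated correlation), namely Trp53inp1 (-0.78), Eda2r (-0.58) and Polk (-0.50). Fibroblast markers were lower in 5 of 11 (6 alone, median log2 -0.45, adjusted p = 0.00157, adjusted p = 0.305 with an estimated correlation), with Dpt -1.73, Pi16 -1.41 and the proteoglycan Dcn -1.32. Interferon genes were lower in 2 of 31 (6 alone, adjusted p = 9.65e-06, adjusted p = 0.338 with an estimated correlation), Gbp2 (-0.95) and the RNA sensor Ddx58 (-0.66). Matrix genes had 3 higher and 4 lower of 30 (3 and 7 alone, median log2 -0.19, adjusted p = 0.0231, adjusted p = 0.496 with an estimated correlation). Postn (0.76), Timp1 (0.70) and Ccn2 (0.70) went against the list's direction. That list call was lost without ERK3-depleted library 1 (adjusted p = 0.0817) or control library 1 (0.0872) and with the length and GC trend removed (0.103). Ribosomal protein genes had 1 of 36 higher, Rpl28 (0.45), and 0 adjusted over the list alone (median 0.22, adjusted p = 5.73e-06, adjusted p = 0.496 with an estimated correlation), and the trend's removal ended that call (median 0.07, adjusted p = 0.0750).

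The number of ERK3 calls in GM depends on single libraries, and folds moved by differing amounts (over 21 alternatives log2 0.50 to 0.69 for Chaf1b and -2.14 to -0.86 for Dpt). With control GM library 2 or ERK3-depleted GM library 1 left out, 0 genes were called (edgeR, against 946), and 73 without control library 3, of the genes named here Chaf1b, Fdps, Insig1, Ddx58, Id1, Scn7a, Itgb4 and H19. Cilp (-1.67), Enpp2 (-1.58) and Rgs17 (-1.55), and Nefl (2.37), Nefm (2.04) and Lrrn1 (1.72), the other largest changes, were lost there too. The counts grew to 1905 with the replicate number as a block and to 1521 by DESeq2, and stood at 45 with adjusted p under 0.01. No gene passed a test for a change over 1.5-fold. Of the 11 list calls made by camera in this comparison, 4 were not made by fry. Gene length went with the fold changes (Spearman -0.339 across genes, which are not independent replicates), and with the length and GC trend removed 587 genes were called.

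Cells depleted of MK5 in growth medium had a like set of changes. Uhrf1, a DNA methylation factor of dividing cells, was 1.71-fold higher (log2 0.78 ± 0.14, n = 3 each, edgeR adjusted p = 0.00631). Cdkn1a was 1.41-fold lower (-0.50 ± 0.09, 192 ± 14.6 against 271 ± 27.8 CPM, adjusted p = 0.00499). Enpp2, which encodes the secreted enzyme autotaxin, was 5.98-fold lower (-2.58 ± 0.39, adjusted p = 0.00306). In all 1178 genes were called, 657 higher and 521 lower, 161 of them over 2-fold.

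Cell cycle genes were higher in 31 of 45 cases and lower in 0 (44 alone, median log2 0.59, camera adjusted p = 1.19e-26, adjusted p = 0.305 with an estimated correlation) in MK5-depleted GM, with Rrm2 at 0.78, Ccne1 at 0.75 and the replication helicase subunit Mcm3 at 0.73. Cholesterol genes were higher in 19 of 25 and lower in 0 (24 alone, adjusted p = 1.14e-19, adjusted p = 0.284 with an estimated correlation), among them Fdps (0.82) and Mvd (0.78). ER stress genes were higher in 12 of 29 and lower in 1 (13 and 2 alone, adjusted p = 2.32e-07, adjusted p = 0.338 with an estimated correlation), with the transcription factor Atf3 at 2.48, Slc7a11 at 1.37 and Vldlr at -1.27. Myogenic regulators were higher in 4 of 21 and lower in 0 (4 alone, adjusted p = 0.0426, adjusted p = 0.496 with an estimated correlation): Msc (2.35), Id2 (0.71), Myod1 (0.61) and Id1 (0.43). That list was not called without MK5-depleted library 1 or 3 or control library 2 (adjusted p = 0.0748, 0.0653, 0.173). Nor was it called with the replicate block (median 0.20, camera adjusted p = 0.0573) or with the length and GC trend removed (median 0.21, 0.0862). Of the sarcomere genes only Des was called (0.34, 0 of 42 adjusted over the list alone, list adjusted p = 0.248), and the mean sarcomere level differed by 0.13 log2 CPM (exact permutation p = 0.7). Fusion genes had Cdh15 (0.68) higher and Rnd3 (-0.38) lower and no list call (adjusted p = 0.958), and no calcium gene was called (Cacna2d1 -0.27, adjusted p = 0.190, list adjusted p = 0.802).

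FoxO targets were lower in 7 of 32 cases and higher in 2 (7 and 2 alone, median log2 -0.12, camera adjusted p = 0.00215, adjusted p = 0.284 with an estimated correlation) in MK5-depleted GM, with the thioredoxin inhibitor Txnip at -0.77, Gadd45a at -0.55 and Sesn3 at -0.52. Fbxo32, a muscle ubiquitin ligase, was 1.36-fold lower (-0.44 ± 0.11, adjusted p = 0.0208), while Trim63 had -0.59 ± 0.34 (adjusted p = 0.321). Autophagy genes were lower in 2 of 31, Map1lc3a (-0.61) and Wipi1 (-0.28), with 0 adjusted over the list alone (list adjusted p = 0.000290, adjusted p = 0.313 with an estimated correlation). Genes of p53 were lower in 5 of 28 and higher in 1 (8 and 1 alone, adjusted p = 0.00753, adjusted p = 0.284 with an estimated correlation), including Trp53inp1 (-0.66) and Eda2r (-0.51). Interferon genes were lower in 3 of 31 (3 alone, adjusted p = 0.00264, adjusted p = 0.496 with an estimated correlation), Gbp2 (-1.03), Gbp3 (-0.69) and Ddx58 (-0.52), a list call lost without control library 2 (adjusted p = 0.162). Fibroblast markers were lower in 5 of 11 (7 alone, adjusted p = 1.66e-05, adjusted p = 0.284 with an estimated correlation), with Dpt -2.16, Pi16 -1.72 and Dcn -1.71. The other largest changes were Nefl (2.47), Stmn4 (2.36), Lrrn1 (2.35) and Nefm (2.20) above control, and Cilp (-2.15), Prg4 (-1.87) and Itgb4 (-1.55) below.

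The number of MK5 calls in GM also depends on single libraries, and over 21 alternatives log2 ran from -0.56 to -0.41 for Cdkn1a, 1.52 to 3.43 for Atf3 and -2.50 to -0.94 for Dpt. Without control GM library 2 42 genes were called, of those named here only Enpp2. The count was 156 without MK5-depleted library 3, 212 without library 1 and 358 without control library 3, and Uhrf1, Fdps, Pi16, Dpt, Cdkn1a, Prg4 and Enpp2 were called in all 3 of these. The replicate block gave 2045 genes, adjusted p under 0.01 gave 221, and no gene passed the test for over 1.5-fold. Gene length did not go with these fold changes (Spearman 0.001 across genes). Of the 9 list calls made by camera in this comparison, 2 were not made by fry.

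**Figure D2:**
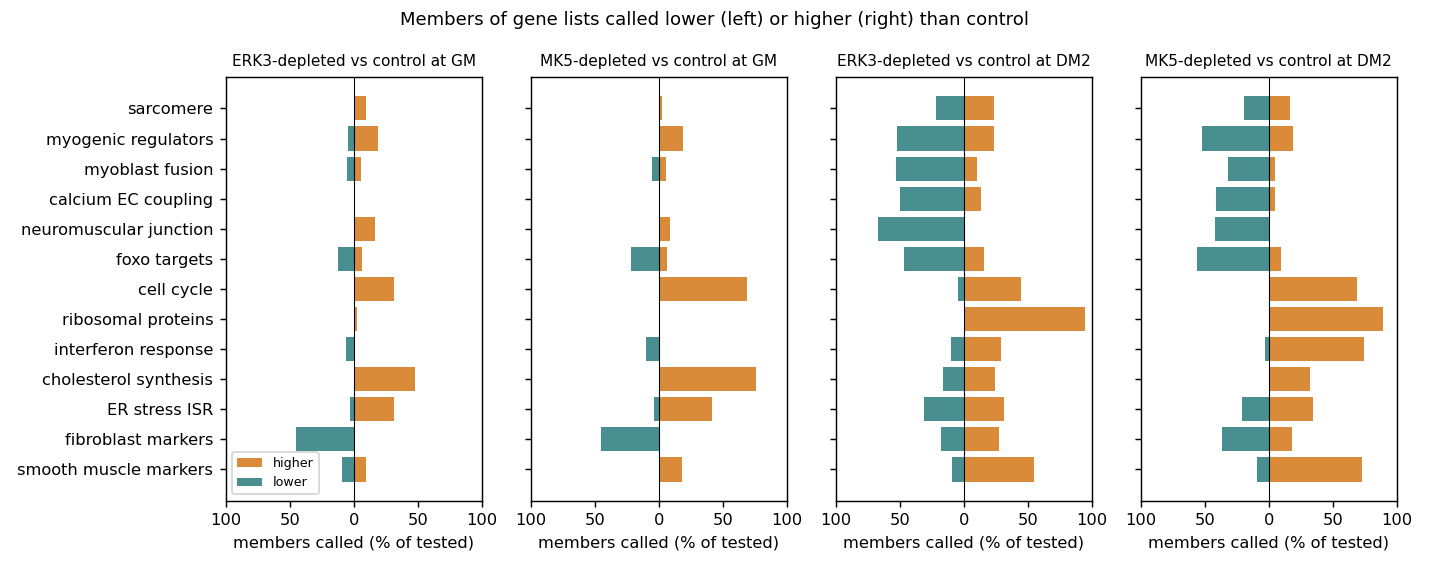
Share of tested members called higher or lower than control in 13 gene lists and 4 depletion comparisons. Bars give percent of members, with 34 of 36 ribosomal protein genes higher in ERK3-depleted DM2.

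**Figure D3:**
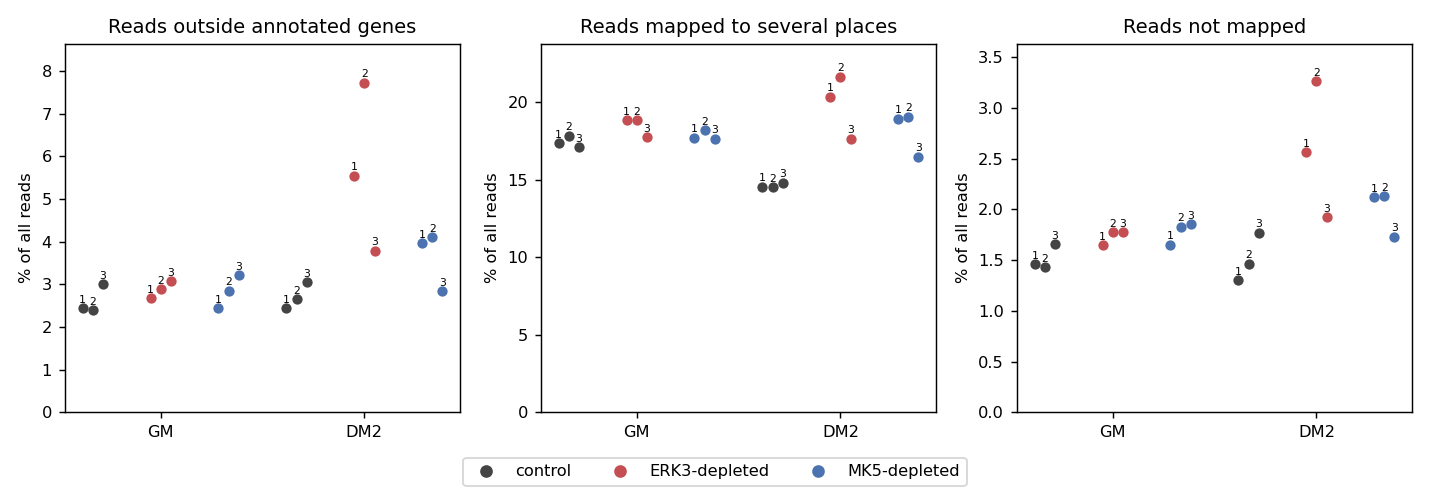
Percent of all reads outside annotated genes (counted without regard to strand), mapping to several places and unmapped, 1 point per library by group. Reads outside genes average 5.69% in ERK3-depleted DM2 and 2.71% in control DM2.

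After 2 days of differentiation the ERK3-depleted cells held more RNA of the proliferation marker Mki67 than control cells, and less of single genes for fusion, the neuromuscular junction and FoxO response. Mki67 was 2.37-fold higher (log2 1.25 ± 0.16, 171 ± 24.9 against 71.9 ± 8.46 CPM, n = 3 each, edgeR adjusted p = 9.79e-06). Mymk, needed for fusion, was 3.62-fold lower (-1.86 ± 0.40, 96.5 ± 39.1 against 350 ± 20.6 CPM, adjusted p = 0.00129), and Ache 6.31-fold lower (-2.66 ± 0.40, adjusted p = 3.36e-05). Pdk4, a metabolic FoxO target, was 2.36-fold lower (-1.24 ± 0.12, adjusted p = 3.09e-06). In all 7776 genes were called, 3905 higher and 3871 lower, 1747 over 2-fold.

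The ERK3-depleted DM2 libraries also differ in read shares that serve here as quality measures. These are not measures of RNA integrity, and what sets them was not tested. Reads outside annotated genes, counted without regard to strand, made up 5.69 ± 1.98% of all reads (5.55, 7.73 and 3.79%), against 2.71 ± 0.308% in control DM2, multimapping reads 19.9 ± 2.04% against 14.6 ± 0.160%, and unmapped reads 2.59 ± 0.670% against 1.51 ± 0.237%. Fold changes fell with gene length (Spearman -0.427 across genes, which are not independent replicates). From GM to DM2 the fold changes rose with length in control (0.289), while the ERK3 line had -0.033. Whether the trend is technical or part of differentiation was not tested, so offsets that remove it may also remove real change. Malat1, a nuclear noncoding RNA, was 47.7-fold higher (5.58 ± 0.78, 6982 ± 5492 against 146 ± 7.98 CPM), or log2 4.81 without ERK3-depleted DM2 library 2. With the share of reads outside genes as a covariate 2704 genes were called, 32.1% of the main calls being shared, and 3651 without the 4 DM2 libraries richest in such reads, a fit that leaves n = 1 in each depleted DM2 group. The values given next for ERK3-depleted DM2 stand beside this difference in read shares. The lowest ERK3-depleted DM2 share (3.79%) lies above the highest of control DM2 (3.05%), so the covariate overlaps with the group itself. A call lost with the covariate can therefore come from a wider error as well as from a smaller effect.

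Cell cycle genes were higher in 20 of 45 cases and lower in 2 (20 and 2 alone, median log2 0.36, camera adjusted p = 0.0256, adjusted p = 0.873 with an estimated correlation) in ERK3-depleted DM2, with the kinetochore motor Cenpe at 1.11, Hmgb2 at 1.05 and Gins2 at 0.95. This list was not called without ERK3-depleted library 3 (adjusted p = 0.526), and on TPM Hmgb2 turned to -0.09 while Cenpe (0.34, adjusted p = 0.128) and Gins2 (0.30, adjusted p = 0.118) were not called. TPM were not scaled between libraries. Foxo3 and Mapk6 stood at 7.57 and 32.4 TPM here against 14.4 and 85.5 in control DM2, a larger fall than on CPM. Calls lost or gained on TPM in this comparison may thus reflect that shift. The shift was larger with the share of reads outside genes as a covariate (29 higher and 0 lower, median 0.72, adjusted p = 1.63e-14). FoxO targets were lower in 15 of 32 and higher in 5 (16 and 6 alone, median log2 -0.23, adjusted p = 0.0245, adjusted p = 0.305 with an estimated correlation), with the pocket protein Rbl2 at -1.22, Klhl24 at -1.10 and Sesn3 at -0.87. That call was lost without library 3 (adjusted p = 0.0760) and with the length and GC trend removed (median -0.14, adjusted p = 0.0985). It was made with the covariate (11 lower and 1 higher, median -0.27, adjusted p = 0.00053). Trim63 was 1.81-fold lower (-0.86 ± 0.16, 8.17 ± 0.796 against 14.8 ± 0.347 CPM, adjusted p = 0.000277). Fbxo32 had -0.26 ± 0.11 (adjusted p = 0.0501), and turned to 0.04 with the length and GC trend removed. Fbxo32 was called by DESeq2 (adjusted p = 0.0419), by voom (0.0492), with RLE size factors (0.0465), without the filter (0.0173), with the CPM filter (0.0369), on TPM (7.37e-05), with only the contrast's libraries (0.0400) and with the replicate block (0.0321).

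Neuromuscular junction genes were lower in 8 of 12 cases and higher in 0 (8 alone, median log2 -0.53, camera adjusted p = 0.0198, adjusted p = 0.496 with an estimated correlation) in ERK3-depleted DM2, among them the receptor kinase Musk (-1.94) and Colq (-1.70). With the covariate that list gave adjusted p = 0.0635. Fusion genes were lower in 10 of 19 and higher in 2 (10 and 2 alone, median log2 -0.28, adjusted p = 0.0466, adjusted p = 0.496 with an estimated correlation), with Dock1 -0.85, Nfatc2 -0.98 and the lipase Mgll 0.99. The fusion list was not called without ERK3-depleted library 1 or 2 (adjusted p = 0.0502, 0.0703). Nor was it called with the length and GC trend removed (median -0.36, camera adjusted p = 0.220) or with the covariate (median -0.12, 0.339). Mymk was not called with the covariate (-0.76, adjusted p = 0.296). Nfatc2 was not called without ERK3-depleted library 1 or 2 (adjusted p = 0.133, 0.0668) or control library 2 or 3 (0.0702, 0.195). Sarcomere genes went both ways (10 higher and 9 lower of 42, 10 and 8 alone, list adjusted p = 0.678), and 7 were higher and 1 lower with the covariate (median turned to 0.32, adjusted p = 0.0638). Xirp2 stood at 2.62 and Tmod4 at 2.12 against Myh2 at -2.25 and Mybpc1 at -1.79, and Xirp2 at 4.55 without control DM2 library 1. The mean sarcomere level was 5.01 ± 0.202 log2 CPM against 5.16 ± 0.072 in control (exact permutation p = 0.4). Myogenic regulators had 11 lower and 5 higher of 21 (11 and 5 alone, median -0.44 but mean -0.08, adjusted p = 0.137). Msc (2.78) and Mef2c (1.41) were above control and Tead4 (-1.04) and Mef2d (-0.78) below. Calcium genes had 11 lower and 3 higher of 22 (11 and 3 alone, adjusted p = 0.123), with Kcnn3 -2.34, Casq2 -1.81 and Srl -1.25 against Trdn 1.74. With the covariate none of these 4 was called (adjusted p = 0.169, 0.116, 0.123, 0.605), nor Nfatc2 (0.257), Mef2c (0.111), Tead4 (0.0805), Tmod4 (0.286) or Myh2 (0.121). As the covariate overlaps with the group, these lost calls do not show that the differences go away. The median of the calcium list was then -0.33, against -0.42 with the replicate block and no covariate.

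Ribosomal protein genes were higher in 34 of 36 cases and lower in 0 (34 alone, median log2 0.92, camera adjusted p = 6.00e-13, adjusted p = 0.313 with an estimated correlation) in ERK3-depleted DM2, led by Rpl13 (1.84) and Rps19 (1.38), the last not called on TPM (0.12, adjusted p = 0.166). The median was 0.33 with the length and GC trend removed (25 higher and 1 lower) and 0.57 with the covariate (25 higher). All 7 tested genes of the mitochondrial genome were higher (7 alone, median log2 1.69, adjusted p = 0.00883, adjusted p = 0.591 with an estimated correlation), with the complex I genes mt-Nd6 (2.29), mt-Nd1 (1.96, 7165 ± 3268 against 1842 ± 230 CPM) and mt-Nd2 (1.94). Both lists are highest in the group with the most reads outside genes. With the covariate 0 of the 7 were called (edgeR, median 0.48, list adjusted p = 0.321). The largest other rises were Kcnq1ot1 (5.05), Hoxc8 (4.30), Neat1 (3.02) and Stmn4 (2.97), and Kcnq1ot1 and Neat1 are nuclear noncoding RNAs like Malat1. Hoxc8 stood at 3.35 and Kcnq1ot1 at 4.35 without ERK3-depleted library 2, and Stmn4 at 4.56 without control library 1. With the covariate Hoxc8 (1.15, adjusted p = 0.207) and Neat1 (1.42, adjusted p = 0.335) were not called. The largest falls were Slc8a1 (-3.17), Atp7a (-3.08), Sntb1 (-2.96), Masp1 (-2.92) and Unkl (-2.85), with Slc8a1 at -4.11, Atp7a at -3.99 and Masp1 at -3.87 without ERK3-depleted library 3.

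Cells depleted of MK5 after 2 days of differentiation likewise held more Mki67 RNA and less RNA of single FoxO targets, and more RNA of interferon response genes. Mki67 was 2.70-fold higher (log2 1.44 ± 0.16, 194 ± 30.3 against 71.9 ± 8.46 CPM, n = 3 each, edgeR adjusted p = 9.69e-06). Pdk4 was 2.70-fold lower (-1.43 ± 0.12, 27.7 ± 3.32 against 74.7 ± 9.03 CPM, adjusted p = 8.94e-07) and Trim63 2.47-fold lower (-1.30 ± 0.17, adjusted p = 2.68e-05). Ifit1, an antiviral interferon target, was 8.44-fold higher (3.08 ± 0.36, 15.4 ± 3.70 against 1.83 ± 0.392 CPM, adjusted p = 1.71e-05). Ifit1 does not set the MK5 line apart. Its response from GM to DM2 differed from control by log2 2.90 in the ERK3 line and 3.28 in the MK5 line, and it was not called between them. In all 6288 genes were called, 3098 higher and 3190 lower, 981 over 2-fold. The quality measures of these libraries lie between the other DM2 groups: 3.64 ± 0.695% of reads outside genes, 18.2 ± 1.45% multimapping and 2.00 ± 0.226% unmapped. Fold changes against control fell with gene length here too (Spearman -0.441 across genes). From GM to DM2 that correlation was 0.289 in control and -0.122 in the MK5 line, so the trend at DM2 is not one of the depleted libraries alone.

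Cell cycle genes were higher in 31 of 45 cases and lower in 0 (32 alone, median log2 0.63, camera adjusted p = 4.66e-09, adjusted p = 0.540 with an estimated correlation) in MK5-depleted DM2, with Cenpe 1.25, Gins2 1.17 and the mitotic kinase Aurka 1.07. FoxO targets were lower in 18 of 32 and higher in 3 (19 and 3 alone, median log2 -0.32, adjusted p = 0.000204, adjusted p = 0.209 with an estimated correlation), with Rbl2 at -1.12 and Klhl24 at -1.05, and Fbxo32 at -0.40 ± 0.11 (adjusted p = 0.00696), which was -0.12 (adjusted p = 0.448) with the length and GC trend removed. Autophagy genes were lower in 12 of 31 and higher in 1 (12 and 1 alone, adjusted p = 0.0201, adjusted p = 0.496 with an estimated correlation), with Atg9a -1.29, the lysosomal membrane protein Lamp2 -0.82 and the kinase Ulk2 -0.72. Atg9a was -0.36 on RSEM counts, still called, and did not pass the test for over 1.5-fold (adjusted p = 0.116). Interferon genes were higher in 23 of 31 and lower in 1 (24 and 2 alone, median log2 0.85, adjusted p = 4.15e-06, adjusted p = 0.313 with an estimated correlation). The chemokine Cxcl10 (2.88) and Ifit3b (2.62) were among them, both under 4 CPM. In ERK3-depleted DM2 9 of the 31 were higher and 3 lower (6 and 3 alone, median 0.26) and the list was not called (adjusted p = 0.142). Smooth muscle markers were higher in 8 of 11 and lower in 1 (8 and 1 alone, adjusted p = 0.00456, adjusted p = 0.305 with an estimated correlation). The contractile genes were Cnn1 4.28-fold, Actg2 2.70-fold and Mylk 1.86-fold above control, the last not called on TPM (adjusted p = 0.0558). Ribosomal protein genes were higher in 32 of 36 (33 alone, adjusted p = 7.96e-13, adjusted p = 0.313 with an estimated correlation), with Rpl13 1.28, Rps19 1.01 (0.14 on TPM, adjusted p = 0.117) and Rpl11 0.95. With the length and GC trend removed 17 of the 36 were higher (median 0.25, against 0.70). Only 3 of 7 mitochondrial genome genes were higher (3 alone) and the list was not called (adjusted p = 0.142).

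Muscle lists were partly lower in MK5-depleted DM2. Calcium genes were lower in 9 of 22 and higher in 1 (11 and 1 alone, median log2 -0.52, camera adjusted p = 0.0245, adjusted p = 0.596 with an estimated correlation), with Casq2 -1.59, Kcnn3 -1.51, Srl -1.12 and the junction protein Jph1 -1.01. Junction genes of the motor endplate were lower in 5 of 12 (5 alone, adjusted p = 0.0284, adjusted p = 0.496 with an estimated correlation), with Ache -1.82, Colq -1.52 and Musk -1.46. Myogenic regulators were lower in 11 of 21 and higher in 4 (11 and 4 alone, adjusted p = 0.0466, adjusted p = 0.496 with an estimated correlation), with Klf5 -1.21 and Tead4 -0.90 against Msc 3.06 and Pitx3 0.87. The calcium and endplate lists were not called without MK5-depleted library 2 (adjusted p = 0.0753, 0.0616), nor the endplate list with the covariate (0.0508), nor the regulators without control library 2 (0.0597). Fusion genes had 6 lower and 1 higher of 19 (6 and 1 alone, adjusted p = 0.157), with Mymk -1.28, Nfatc2 -0.98, the N-cadherin Cdh2 -0.88 and Mgll 0.74. Mymk (143.6 ± 71.96 CPM) was not called without MK5-depleted library 1 or 2 (adjusted p = 0.0693, 0.0689), Kcnn3 without library 1 or 2 (0.0635, 0.0519), and Nfatc2 without library 1 (0.197) or control library 2 or 3 (0.0854, 0.218). Sarcomere genes had 7 higher and 8 lower of 42 (7 and 8 alone, adjusted p = 0.750). Xirp2 had 2.22 against Mybpc1 -1.67 (-0.38 on TPM, adjusted p = 0.0955), Myh2 -1.63 and Lmod2 -1.42, and Xirp2 at 4.16 without control library 1. The other largest changes were Kcnq1ot1 (3.68), Malat1 (3.67) and Siglecg (2.91, or 4.37 without control library 1) upward. Downward went Lnpep (-2.28), Omd (-2.28), Sntb1 (-2.24), Klhl11 (-2.22) and Atp7a (-2.19), with Sntb1 at -2.93, Klhl11 and Atp7a both at -2.82 and Kcnn3 at -2.26 without MK5-depleted library 3.

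Both depleted lines also raised sarcomere RNA and lowered cell cycle RNA on differentiation. The sarcomere list rose in 40 of 42 genes and fell in 0 in each (40 and 41 rising alone, camera adjusted p = 1.44e-19 for ERK3 and 1.72e-26 for MK5, adjusted p = 0.305 and 0.284 with an estimated correlation), its mean level going from 2.28 ± 0.357 to 5.01 ± 0.202 log2 CPM in the ERK3 line and from 1.78 ± 0.397 to 5.04 ± 0.307 in the MK5 line (exact permutation p = 0.1 each). Cell cycle genes fell in 43 and 44 of 45 (44 and 44 alone, adjusted p = 1.18e-15 and 4.08e-14, adjusted p = 0.422 and 0.463 with an estimated correlation). From GM to DM2 7680 genes changed in the ERK3 line (4023 up and 3657 down) and 6876 in the MK5 line (3425 up and 3451 down, edgeR). Of the 3140 genes that rose in control, 1915 rose and 159 fell in the ERK3 line and 1871 rose and 111 fell in the MK5 line. Over 10651 genes called in any line the principal-axis slope of each response against that of control was 1.075 ± 0.355 for ERK3 (jackknife standard error, 1.45 without ERK3-depleted DM2 library 3) and 1.002 ± 0.102 for MK5, with r of 0.637 and 0.742 across genes that are not independent replicates.

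The change from GM to DM2 itself differed from control for 3983 genes in the ERK3 line (2033 more upward, 1950 more downward, edgeR interaction) and 2512 in the MK5 line (1190 and 1322). Casq2 rose less in both (interaction log2 -2.75 ± 0.56, adjusted p = 0.00446, and -1.82 ± 0.58, adjusted p = 0.0414), as did Pdk4 (-1.02 ± 0.16 and -1.20 ± 0.17). With the covariate Casq2 was not called in the ERK3 line (-1.99, adjusted p = 0.0989), nor did it pass the test for over 1.5-fold (0.0641). The Casq2 value of the MK5 line and those of Pdk4 and Mymk were not tested under the alternatives. Mymk rose less in the ERK3 line (-2.42 ± 0.62, adjusted p = 0.0118), and the MK5 value was -1.16 ± 0.63 (adjusted p = 0.198). Ifit1 went the other way (2.90 ± 0.50 and 3.28 ± 0.49, adjusted p = 0.00251 and 0.00233). Foxo3 had -0.04 ± 0.13 and -0.15 ± 0.13 (adjusted p = 0.855 and 0.427). The ERK3 count was 200 with the covariate, and 2556, 2459 and 2537 without ERK3-depleted DM2 library 1, 2 or GM library 3. The MK5 count was 987 without MK5-depleted DM2 library 1, 1168 and 879 without GM library 1 or 3, 1656, 1282 and 1466 without control DM2 library 1, 2 or 3, 1032 without control GM library 2, and 1118 with the length and GC trend removed. As many genes were called in 9 of 100 splits of the libraries for each interaction, the real grouping among them. All 9 left the real DM2 groups whole, as only 12 of the 100 splits did for ERK3 and 13 for MK5. Most splits that regrouped the GM libraries alone thus gave as many genes as the real grouping.

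Between the depleted lines no gene was called in either medium. In GM the edgeR count was 0 (1167 genes at an unadjusted p under 0.05, smallest adjusted p 0.362), with 11 by DESeq2 and 0 by voom. At DM2 it was 0 (2741 unadjusted, smallest adjusted p 0.0560), with 214 by DESeq2, 2 by voom, 368 with the replicate block and 3597 without ERK3-depleted DM2 library 3. Some lists were called without any member called: cell cycle genes were shifted upward in MK5-depleted relative to ERK3-depleted cells (median log2 0.13 in GM and 0.30 at DM2, camera adjusted p = 0.000618 and 2.00e-11, adjusted p = 0.714 and 0.496 with an estimated correlation). Sarcomere genes were shifted downward in GM (-0.62, adjusted p = 8.27e-12, adjusted p = 0.381 with an estimated correlation), and interferon genes upward at DM2 (0.54, 12 of 31 alone, adjusted p = 2.49e-09, adjusted p = 0.284 with an estimated correlation). Fry made none of the 8 list calls in GM (adjusted p = 0.546 for cell cycle and 0.132 for sarcomere) and 1 of the 7 at DM2 (interferon, 0.00518, with cell cycle at 0.132). The mean sarcomere level differed by -0.50 log2 CPM in GM (exact permutation p = 0.3) and 0.03 at DM2 (0.9). The GM cell cycle call was lost without ERK3-depleted GM library 2 (adjusted p = 0.0662), and the DM2 one with the share of reads outside genes as a covariate (0.271). With that covariate the DM2 sarcomere list was called downward (median -0.27, adjusted p = 1.03e-06), against an uncalled upward value without it (adjusted p = 0.778).

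The ERK3 and MK5 fold changes against control resemble each other, with r = 0.702 in GM and 0.903 at DM2 over 13939 genes that are not independent replicates. In GM 333 genes were higher and 214 lower in both (24.5 and 16 if the calls were independent), and at DM2 2697 and 2790 (868 and 886), with 0 genes called in opposite directions in either medium. Part of this may come from the 3 control libraries that both comparisons share. Groups simulated without any change against shared controls gave a mean r of 0.492 and 0.470 and a covariance of at most 0.0363 and 0.0350 in 100 draws. The observed covariance was 0.0965 in GM and 0.402 at DM2 on the same genes. The draws take libraries as independent, so they leave out the resemblance of libraries with the same replicate number.

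**Figure D4:**
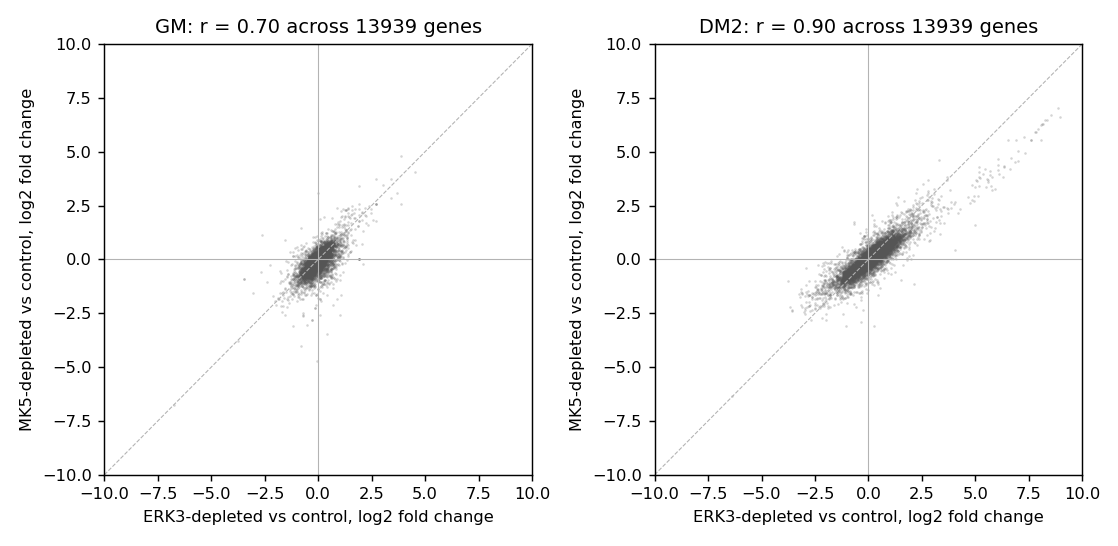
Log2 fold changes against control of the MK5 line plotted against those of the ERK3 line, in GM and at DM2. Each point is 1 of 13939 genes, and r is 0.702 in GM and 0.903 at DM2.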

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

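The tests of gene length and GC content, shared controls, control-line state and blood cells were chosen after seeing results, while what the splits and the covariate should show was written before their own results, the covariate itself having been chosen after seeing the data.

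The genes that differ between ERK3-depleted and control cells at DM2 move with the share of reads outside genes. Of the called genes 74.3% stayed called in the same direction with the length and GC trend removed under the replicate block, and the slope of the fold changes with the covariate on those without was 0.654. For MK5 at DM2 61.8% stayed called with the length and GC trend removed and no block, and the slope was 0.911. Only the ERK3 share has the block, so the shares of both lines cannot be compared. A part of the ERK3 difference thus goes with this share, while neither test accounts for all of it. Whether the share reflects library quality or depletion cannot be told. The 3 ERK3-depleted libraries all lie above control in such reads counted without regard to strand.

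The resemblance of the ERK3 and MK5 effects had a covariance of 0.0965 in GM and 0.4016 at DM2. Both lie above the highest of the simulated draws with shared controls (0.0363 and 0.0350), which take libraries as independent. The labels name 1 control line and do not say whether its replicates are separate clones. A peculiar state of the control cells could produce the same resemblance, and this cannot be decided here.

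Interferon genes fell from GM to DM2 in control cells (25 of 31 lower, median log2 -1.18 with the replicate block), so MK5-depleted DM2 is set against a fallen control. There the level above control held for 17 genes with the length and GC trend removed and had a median log2 of 0.806 with the covariate. Neither the length and GC trend nor the covariate thus accounts for all of it. Of tested blood markers 33.33% were called higher, Csf1r (1.30) and Fcer1g (2.30), beside 3098 of all 13939 tested genes. These markers held only 1.17 and 0.417 CPM in MK5-depleted DM2, so their share decides little. Ptprc, Tyrobp and Adgre1 had 0 CPM there, which argues against blood cells as the source.

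Among the 10 splits of each 3 against 3 contrast, only the real 1 gave as many calls for the 3 contrasts of DM2 with GM and the 4 of depletion with control, the highest others being 515 for the ERK3 line's DM2 against GM (real 7680), 1 for ERK3 against control at DM2 (real 7776) and 0 for the rest. The splits are too few for a share under 0.05. Between the depleted lines the real count is 0, so 10 of 10 splits must give as many in each medium and the test says nothing there (highest others 0 in GM and 2243 at DM2). For the interactions 9 of 100 splits, the real grouping among them, gave as many genes as the real 3983 for ERK3 and 9 of 100 as many as the real 2512 for MK5 (highest others 6930 and 3895). All of these left the real DM2 groups whole, which only 12 of the 100 splits did for ERK3 and 13 for MK5. The highest with mixed DM2 groups was 1, so the interaction counts cannot be told from the DM2 difference by this test.

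The response to differentiation differed by line for 3983 genes (ERK3) and 2512 (MK5), and the cause was not tested. Among the lists called in the interactions, interferon, ribosomal proteins, mitochondrial genome and smooth muscle were shifted upward and all others downward. Fry did not make 4 of the 11 ERK3 and 4 of the 10 MK5 list calls. List tests by camera for the ERK3 interaction gave adjusted p = 0.0003395 for sarcomere, 0.003127 for myogenic regulators, 0.03 for fusion, 0.01882 for calcium handling, 0.0002044 for the neuromuscular junction, 6.232e-05 for interferon, 0.01153 for ER stress, 0.0003481 for cholesterol, 4.871e-10 for ribosomal proteins, 0.0004378 for the mitochondrial genome and 0.01896 for smooth muscle (adjusted p = 0.305 to 0.622 with an estimated correlation). The fusion call ended with length and GC offsets (0.141), with these and the replicate block (0.0878) and with the covariate (0.248). Its median log2 was -0.43 with offsets and -0.24 with the covariate, against -0.51 with the block alone. The calls of calcium handling and smooth muscle ended without ERK3-depleted DM2 library 3 (0.0778, 0.0764). For the MK5 interaction they gave 0.0005764 for myogenic regulators, 0.04183 for calcium handling, 0.0003481 for the neuromuscular junction, 0.03126 for FoxO targets, 1.637e-11 for interferon, 0.02893 for ER stress, 0.0003072 for cholesterol, 2.645e-11 for ribosomal proteins, 0.04183 for the mitochondrial genome and 0.006521 for smooth muscle (adjusted p = 0.284 to 0.665 with an estimated correlation). With length and GC offsets the ribosomal median was 0.17 and 1 of 36 members was called (camera adjusted p = 0.0125), against 0.59 and 27 members with the block alone. In the ERK3 interaction the offsets left a ribosomal median of 0.27, with 12 members higher and 1 lower. The mitochondrial call of the MK5 interaction ended in 7 fits with a library left out (0.0537 to 0.138) and with the covariate (0.0714). Leaving a library out ended the calcium call in 5 fits (0.0626 to 0.116), the ER stress call in 5 (0.0631 to 0.0748) and the FoxO call in 2 (0.0641, 0.0892). ER stress had 0.0508 with the covariate, and FoxO targets had 0.202 with offsets, 0.257 with offsets and block and 0.0502 with the block.

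ERK3 interaction values above 0 (log2, edgeR) were 5.031 for Kcnq1ot1, 4.878 for Malat1, 3.834 for Hoxc8, 2.956 for Neat1, 2.902 for Ifit1, 2.816 for mt-Nd6. Below these came 2.509 for Tmod4, 2.374 for mt-Nd2, 2.268 for mt-Nd1, 1.876 for Pi16, 1.611 for Rpl13, 1.572 for Scn7a, 1.147 for Rps19, 0.994 for Mki67, 0.87 for Cenpe and 0.415 for Gins2. Values below 0, where the response was less upward or more downward than in control, were -0.575 for Sod2, -0.599 for Dock1, -0.702 for Mapk6, -0.724 for H19, -0.783 for Myod1, -0.794 for Mef2d, -0.962 for Rrm2, -1.02 for Pdk4, -1.054 for Klhl24, -1.083 for Rbl2, -1.14 for Asns, -1.251 for Tead4, -1.268 for Id2, -1.299 for Insig1 and -1.589 for Srl. Further below 0 were -2.075 for Musk, -2.099 for Masp1, -2.22 for Mybpc1, -2.425 for Mymk, -2.453 for Unkl, -2.563 for Slc8a1, -2.719 for Atp7a, -2.753 for Casq2, -2.871 for Tmem182, -2.976 for Lmod2, -3.016 for Myoz2, -3.126 for Sntb1 and -3.873 for Kcnn3.

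MK5 interaction values above 0 were 3.4 for Cxcl10, 3.322 for Kcnq1ot1, 3.283 for Ifit1, 3.255 for Malat1, 2.917 for Ifit3b. Next were 2.212 for Prg4, 2.203 for Pi16, 1.782 for Dpt, 1.482 for Cnn1, 1.363 for Gbp3, 1.316 for Mylk, 1.198 for Map1lc3a, 1.162 for Rpl13, 0.992 for Actg2, 0.957 for Rps19, 0.877 for Mki67, 0.818 for Rpl11, 0.66 for Cenpe and 0.591 for Gins2. Values below 0 were -0.544 for Ulk2, -0.587 for Lamp2, -0.674 for Myod1, -0.725 for Mapk6, -0.833 for Rrm2, -0.872 for Klhl24, -0.993 for Cdh2, -1.017 for Rbl2, -1.097 for Srl, -1.197 for Pdk4, -1.248 for Jph1, -1.254 for Klf5 and -1.308 for Tead4. Further below 0 were -1.41 for Atg9a, -1.546 for Id2, -1.717 for Musk, -1.824 for Casq2, -2.074 for Lmod2, -2.201 for Sntb1, -2.313 for Lnpep, -2.324 for Atp7a, -2.453 for Klhl11 and -2.48 for Zfp871.

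In the quality measures all ERK3-depleted DM2 libraries lay above control DM2. Their means were 5.687% of reads outside genes (counted without regard to strand), 19.87% multimapping and 2.585% unmapped. On reverse counts ERK3-depleted library 3 had 5.54% of reads outside genes, under control library 1 (5.78%). Multimapping was also above control DM2 in MK5-depleted DM2 (18.151%), but near the GM groups (17.4 to 18.5%), so that control DM2 is the low group (14.6%). The cause was not tested.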

How the results depend on the processing

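The tests on unstranded counts, with length and GC offsets, with the covariate and without 4 DM2 libraries were chosen after seeing results. The last leaves n = 1 in each depleted DM2 group, so its counts rest on the spread of other groups. All values here are edgeR unless another tool is named, and the cause was not tested. Values on TPM are from limma-trend without scaling between libraries. Genes called for ERK3 against control in GM (main 946) were 1521 by DESeq2, 1482 without the filter, 1905 with the replicate block, 45 with adjusted p under 0.01, 0 with glmTreat, 36 on TPM, 587 with length and GC offsets, 1739 with these and the block, 1668 with the covariate and 0 to 1101 with a library left out. For MK5 in GM (main 1178) they were 2045 with the block, 221 with adjusted p under 0.01, 0 with glmTreat, 168 on TPM, 2622 with offsets and block, 1869 with the covariate and 42 to 1392 with a library left out. At DM2 the ERK3 count (main 7776) was 1665 with glmTreat, 2704 with the covariate and 3651 without the 4 libraries, and the MK5 count (main 6288) was 4182 with adjusted p under 0.01 and 450 with glmTreat. Between the depleted lines (main 0) GM gave 11 by DESeq2, 165 without the filter, 1 on RSEM counts and 0 to 1 with a library left out. DM2 gave 214 by DESeq2, 2 by voom, 1331 without the filter, 368 with the block, 872 with offsets and block, 3 without the 4 libraries and 0 to 3597 with a library left out. DM2 against GM under glmTreat gave 1606 in control, 2103 in ERK3-depleted and 1467 in MK5-depleted cells, and the ERK3 count was 3720 with the covariate and 4721 without the 4 libraries. The ERK3 interaction (main 3983) was 1496 with adjusted p under 0.01, 20 with glmTreat, 5977 on TPM, 200 with the covariate, 641 without the 4 libraries and 2459 to 5835 with a library left out. The MK5 interaction (main 2512) was 3870 with only the contrast's libraries, 366 with adjusted p under 0.01, 6 with glmTreat, 1118 with offsets and 879 to 3008 with a library left out.

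Mapkapk5 in MK5-depleted DM2 had log2 -0.683 by DESeq2, -0.081 on RSEM counts and -0.825 to -0.495 with a library left out (-0.729, -0.655 and -0.537 between), and in MK5-depleted GM -0.675 on RSEM counts. In the ERK3 line it was 0.107 on RSEM counts and 0.101 on TPM in GM and 0.299 on RSEM counts at DM2. Trim63 in ERK3-depleted GM was -0.011 on RSEM counts, -0.014 on TPM, -0.001 with offsets, -0.002 with offsets and block, and -0.228 to 0.289 with a library left out (-0.184 between). Foxo3 on control differentiation was -0.292 with offsets, -0.291 with offsets and block, and -0.002 to 0.109 with a library left out. Fbxo32 in ERK3-depleted DM2 was 0.036 with offsets and 0.035 with offsets and block. Hmgb2 there was -0.089 on TPM, and Slc7a11 was -0.002 on TPM in MK5-depleted GM and -0.440 on unstranded counts on control differentiation.

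List tests called numbered 0 with an estimated correlation (main 111). The replicate block ended the list calls of myogenic regulators in GM (adjusted p = 0.0571 for ERK3 and 0.0573 for MK5) and FoxO targets in the MK5 interaction (0.0502), brought in cell cycle genes downward in the ERK3 interaction (median -0.26, adjusted p = 0.0341), where the covariate gave an upward call (0.27, adjusted p = 0.0262), and changed no other list call named in the text. The correlation of both depletions in GM (main 0.702) was 0.9152 over genes called in either and 0.6716 to 0.7554 with a control library left out. At DM2 (main 0.903) it was 0.9330 over called genes, 0.9075 with the 1 CPM filter, 0.8903 with length and GC offsets and 0.9099 to 0.9161 with a control library left out (0.9129 between). The response size of the ERK3 line ran from 0.9921 to 1.4501 with a library left out.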

Other observations

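The tests with length and GC offsets and with the covariate mentioned here were chosen after seeing results.

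Markers of other cell types gave no list call on control differentiation. Adipocyte markers fell in 3 of 6 and rose in 0 (3 alone, camera adjusted p = 0.0735), osteoblast markers fell in 4 of 9 and rose in 2 (4 and 2 alone, adjusted p = 0.158), and haematopoietic markers fell in 2 of 6 (2 alone, adjusted p = 0.0905). Fibroblast markers rose in 3 and fell in 4 of 11 (3 and 4 alone), with a median log2 of -0.21 and a mean of 0.05, and smooth muscle markers rose in 4 and fell in 3 of 11 (4 and 3 alone, median -0.18, adjusted p = 0.907). Endothelial (3 of 4 lower), epithelial (2 of 3) and neuronal (2 of 4) markers were too few for a list test. Genes of p53 rose in 9 of 28 and fell in 5 (10 and 7 alone, adjusted p = 0.345).

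Genes of the ERK pathway went both ways at DM2 in both depletions. MAPK kinase genes rose in 3 and fell in 4 of 17 on control differentiation (3 and 4 alone, camera adjusted p = 0.625), none was called for either depletion in GM (adjusted p = 0.418 for ERK3 and 0.992 for MK5), and at DM2 4 were higher and 5 lower for ERK3 (4 and 5 alone, adjusted p = 0.972) and 3 higher and 4 lower for MK5 (3 and 2 alone, adjusted p = 0.987). For ERK feedback genes 6 of 27 were higher and 8 lower for ERK3 at DM2 (6 and 8 alone, adjusted p = 0.851) and 6 higher and 5 lower for MK5 (6 and 5 alone, adjusted p = 0.460). They rose in 15 and fell in 5 on control differentiation (15 and 7 alone, adjusted p = 0.0701) and rose in 15 and fell in 3 in the MK5 line (15 and 3 alone, adjusted p = 0.00746, adjusted p = 0.496 with an estimated correlation).

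The RNA of more FoxO targets was lower than higher in both depleted lines at DM2, though neither list was called with an estimated correlation (adjusted p = 0.305 for ERK3 and 0.209 for MK5). Foxo3 RNA was lower in the MK5 line. In the ERK3 line its call (-0.37) ended with the length and GC trend removed (-0.15, adjusted p = 0.124) and with the covariate (-0.17, adjusted p = 0.338). There the list was called with the covariate (median -0.27, adjusted p = 0.00053), although the slope of the fold changes over all genes was 0.654. It was not called with the length and GC trend removed (-0.14, from -0.23), so that trend, technical or not, could account for a part of it. In the MK5 line the list was called with that trend removed (-0.22, adjusted p = 0.00146). FoxO3 protein, ERK3 protein and MK5 protein were not analysed here.

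To part depletion from the state of single lines would take more control and depleted lines and replicate cultures stated as such. DM2 libraries of matched read shares would also be needed. The labels name 1 control line. Splice forms, edited sites and reads outside genes were not analysed here.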
